A study of Mus musculus with 6 samples.

How the data were processed

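Gene expression was measured by RNA sequencing in 6 libraries of N2A-A5 cells, described as acceptor cells in the labels. N2A (Neuro-2a) is a mouse neuroblastoma cell line. Of the 6 libraries, 3 came from undifferentiated cells (0 h), grown in 10% fetal bovine serum with blasticidin, and 3 from cells kept for 96 h in differentiation medium with 1% serum and 10 µM retinoic acid and without blasticidin. The design text calls the 3 libraries of each group biological replicates. Retinoic acid, the lower serum, the end of blasticidin and the time in culture changed together, so no comparison made here separates them.

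Per the labels' protocols, total RNA was depleted of ribosomal RNA, libraries were prepared with a stranded total RNA kit (Takara SMARTer Stranded Total RNA-Seq v2, Pico) and sequenced as paired ends on a Singular Genomics G4 instrument. Per the submitters' processing notes, FastQC 0.12.1, Salmon 1.10.1 and DESeq2 1.52.0 were used with the mouse build mm39. The role of each tool, the annotation, the strand setting and how transcripts were summed to genes are not given in the sources used here. The deposited table holds estimated counts (expected counts, which need not be whole) for 40413 genes, not normalised, with the gene symbol as both identifier and name in all 40413 rows. Genes that share reads with near-identical copies, such as histone, MHC and small nucleolar RNA genes, and overlapping or antisense genes are uncertain, because estimation can split their reads.

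Totals ran from 16.8 M to 20.9 M counts per library (M for mega). Counts were rounded to whole numbers before testing. In edgeR 4.0.16 (R 4.3.3), genes with too few counts were removed with filterByExpr, which left 13705 genes, libraries were scaled with TMM factors, and the groups were compared with the quasi-likelihood F test. The Benjamini-Hochberg adjusted p threshold was 0.05. The standard error of a log2 fold change is its size divided by the square root of F. Depth-scaled counts (CPM) use the TMM-scaled library sizes. In simulated libraries with the real 0 h means in both groups and the real dispersions (12972 genes run), the test recovered 85% of 100 genes changed 2-fold and 61% of 100 genes changed 1.41-fold, and 12 of its 158 calls (7.59%) were false, above the nominal 5 in 100. This was a single simulated set in which no other genes changed, whereas 7869 genes passed in the data. The changed genes were not drawn from those with the lowest 0 h levels. These shares therefore need not hold for the real comparison.

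A set of 31 gene lists, holding 846 genes, and 24 key genes were fixed before the data were examined. The lists cover retinoid metabolism, HOX genes, neuronal cytoskeleton, synapse, dense-core vesicles, ion channels, catecholamine, cholinergic and amino acid transmitter identity, neurogenic factors, progenitor and Notch genes, splicing regulators, guidance and neurotrophic signalling, DNA replication, mitosis, CDK inhibitors and p53 targets, sterol and fatty acid synthesis, immediate-early genes, the integrated stress response, interferon genes, extracellular matrix, glycolysis, oxidative phosphorylation, ribosome biogenesis, lysosome, and markers of 5 other kinds of cell. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. The text names the key genes, the 10 genes with the largest rise and the 10 with the largest fall, and from each list the 2 higher and 2 lower members with the smallest adjusted p. Some genes that this rule takes are not reported here. The genes with the largest changes had to pass the test, have libraries that did not overlap and reach a mean of 5 CPM in the higher group. Predicted, clone-named, mitochondrially encoded and ribosomal RNA genes were left out of them.

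Shares of counts were compared with an exact two-sided permutation test, which cannot go below 0.1 with 3 libraries against 3. Where a group had 0 counts, the fold was computed against a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with an exact 95% conditional binomial interval. Floors and intervals cover counting error only. No pair of libraries of a group agreed within sampling noise: the chi-square per degree of freedom ran from 6.79 to 13.9, and each library was counted once.

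Gene biotypes, RNA lengths and transcript GC content came from annotations of GRCm38.p6 (RefSeq) and GRCm38 (GENCODE M21), an earlier build than that of the counts. They were matched by symbol, 13123 of the 13705 tested genes had a RefSeq biotype, and no coordinates are given. Alternatives planned in advance were other scalings (DESeq2 size factors, upper quartile, library size only), no filter or a stricter one, the Wald test of DESeq2 1.42.0, limma-voom, an adjusted p of 0.01, a test against a 1.5-fold change, removal of mitochondrial, ribosomal RNA and small nuclear RNA genes, a block for the replicate number, leaving out each library, and for lists an estimated correlation, fry and a prior count of 0.5. A fit on protein-coding genes alone, and list medians after removal of a GC and length trend fitted on coding genes, were added after seeing the data.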

Results

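The 6 libraries held 17.6 M, 20.9 M and 18.2 M counts at 0 h and 16.8 M, 19.0 M and 18.8 M counts at 96 h (replicates 1, 2 and 3, with M for mega). Of 40413 genes, 13919 had 0 counts in all libraries and 13705 were tested. The comparison asks how the transcriptional programme of N2A-A5 cells differs between the undifferentiated state and 96 h of differentiation in low serum with retinoic acid.

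The libraries of the 2 states differed in makeup. Nuclear protein-coding genes took 64.9% ± 2.0 of counts at 0 h and 49.3% ± 1.9 at 96 h (mean ± SD, n = 3 libraries each, as for all means here). The predicted gene Gm26917 took 20.2% ± 2.2 at 0 h and 30.5% ± 1.6 at 96 h, and whether it shares sequence with ribosomal RNA was not tested. Mitochondrial ribosomal RNA took 8.05% ± 0.81 and 9.40% ± 0.37, mitochondrial mRNA 1.38% ± 0.19 and 1.90% ± 0.09, and nuclear-encoded structural RNA (snoRNA, snRNA, tRNA and similar genes) 2.71% ± 0.31 and 5.71% ± 0.24. The 10 most abundant genes together took 32.7% ± 2.0 and 46.3% ± 1.8. For each of these 6 shares the libraries of the 2 groups did not overlap (exact permutation p = 0.1, the smallest possible). Totals (exact permutation p = 0.6) and the number of genes with at least 1 count, 19100 ± 1108 and 20735 ± 584 (exact permutation p = 0.2), overlapped between the groups.

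**Figure D1:**
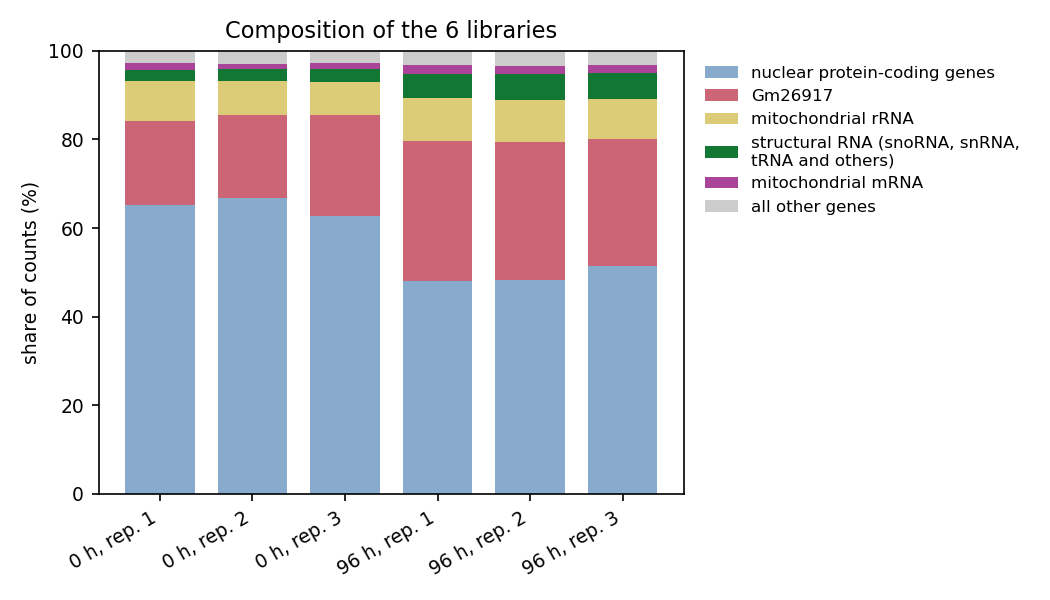
Share of counts (%) per library in each class of genes, as stacked bars for the 3 libraries at 0 h and the 3 at 96 h. The mean share of nuclear protein-coding genes was 64.9% at 0 h and 49.3% at 96 h, and that of Gm26917 20.2% and 30.5%.

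Between 0 h and 96 h, DNA replication genes such as Pcna fell, stress response genes such as Ddit3 and Slc7a11 rose, and neuronal genes moved in both directions. At an adjusted p under 0.05 (edgeR), 3927 genes were higher and 3942 lower at 96 h, and 5836 did not pass. By at least 2-fold, 1608 were higher and 517 lower. Among 11797 protein-coding genes, 3202 were higher and 3787 lower, 1047 and 462 of them by at least 2-fold. Libraries of the 2 groups did not overlap for 8785 genes (64.1%, where chance gives 10%). With scaling by library size only, which lowered the median log2 fold change of all genes by 0.25 relative to TMM (a shift of -0.25), 2409 genes were higher and 5849 lower, so that 29.2% of calls were higher in place of 49.9%. Directions here are relative to the TMM scale, and pairs of counts marked with library size only are the higher and lower members of a list under that scaling.

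Several of the genes with the largest rises were at or near 0 counts at 0 h. Calcb, which encodes the beta form of calcitonin gene-related peptide, had 0 counts at 0 h and 10.8 ± 1.4 CPM at 96 h, at least 222-fold higher (floor of 3 counts over the group). Elmo1 was at least 125-fold higher and Snord50b at least 363-fold higher. Csn3, the gene of kappa-casein, had 3 counts at 0 h and 3245 at 96 h, a ratio of 1339 (95% interval 458 to 6495). The ratio was 613 (169 to 5071) for Spp1, which encodes osteopontin, 519 (92.6 to 20531) for Plcl1, 354 (63.0 to 14029) for G0s2, 351 (96.9 to 2909) for H2-M10.1 and 188 (51.5 to 1555) for Traf3ip3. Lef1, a transcription factor of Wnt signalling, went from 0.137 ± 0.13 to 46.7 ± 1.3 CPM (log2 fold change 8.27 ± 0.22, SE). Snord50b and H2-M10.1 are uncertain, because they share reads with overlapping or related genes.

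The largest falls included both subunits of the 5-HT3 serotonin receptor. Htr3a went from 202 ± 6.2 to 4.60 ± 0.50 CPM (log2 fold change -5.46 ± 0.08, SE) and Htr3b had a log2 fold change of -5.18 ± 0.27. Ahnak went from 415 ± 16 to 22.0 ± 1.1 CPM (-4.24 ± 0.06). Genes of the contractile and actin-binding apparatus were among the 10: Acta2 (smooth muscle actin, -4.13 ± 0.27), Pdlim3 (-4.12 ± 0.35), Tnnt2 (cardiac troponin T, -3.51 ± 0.26) and Cnn2 (calponin 2, -3.01 ± 0.13). Bambi, a pseudoreceptor of TGF-beta family signalling, fell by 3.41 on the log2 scale, H1f1, a linker histone gene with near-identical relatives, by 3.31 and Nckap5 by 3.08. All 20 of these genes passed the test.

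**Figure D2:**
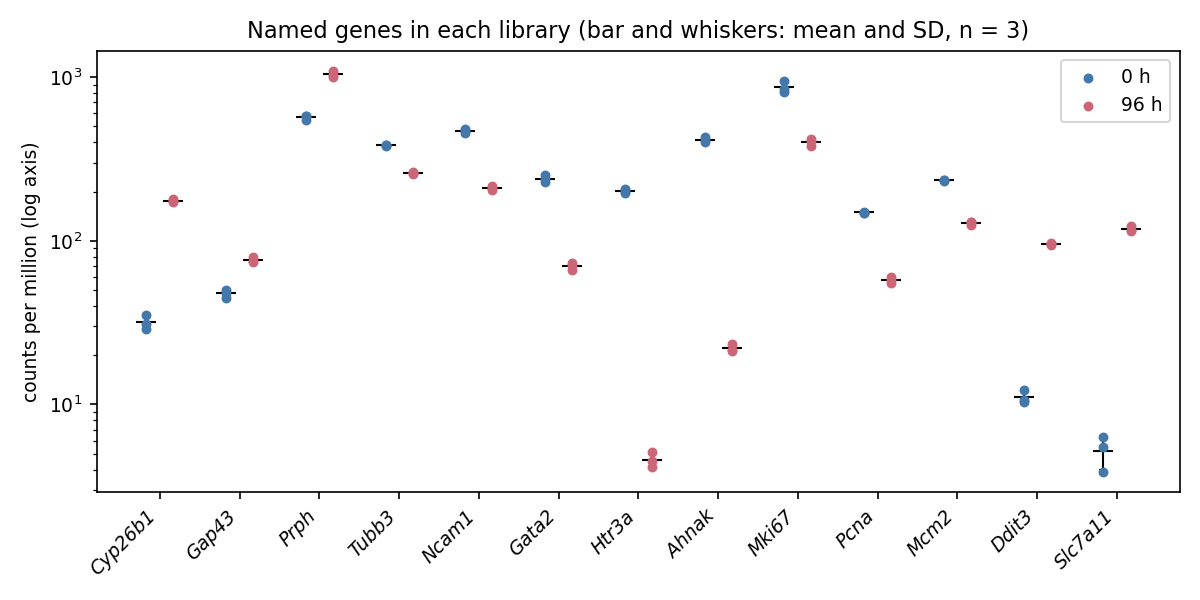
CPM (log axis) of 13 named genes in each library at 0 h and 96 h, with points for libraries and black bars and whiskers for the mean and SD (n = 3). Htr3a went from 202 to 4.60 and Slc7a11 from 5.21 to 119 CPM.

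Retinoid genes moved in both directions. Cyp26b1, an enzyme that degrades retinoic acid, rose 5.54-fold, from 31.8 ± 3.3 to 176 ± 3.2 CPM (log2 fold change 2.47 ± 0.07, edgeR adjusted p = 6.6e-12). Rarg rose (0.77 ± 0.08), and Rara (-0.88 ± 0.08) and Rxrb (-0.29 ± 0.11) fell. The call of Rxrb (edgeR adjusted p = 0.0369) was lost when any of 0 h replicate 3 and the 3 libraries at 96 h was left out, with upper-quartile factors (0.118) and with limma-voom (0.0628). Of 9 tested members, 5 were higher and 2 lower (3 and 2 with library size only), and camera did not pass (adjusted p = 0.377). Other widely used retinoic acid targets were close to 0 in every library: Rarb had 0 counts at 0 h and 1 at 96 h, Cyp26a1 had 2 and 3, Dhrs3 had 1 and 2 and Crabp2 had 5 and 9, and without the low-count filter none of the 4 passed (edgeR adjusted p = 0.521 to 0.792). Of 9 tested HOX genes and cofactors, Meis1 (0.98 ± 0.08) and Hoxc4 (1.34 ± 0.22) rose and 3 fell, Nr2f2 (-0.56 ± 0.07) among them. The list held 23 genes. Hoxa2, Hoxa3, Hoxa5, Hoxb2, Hoxb3, Hoxb4, Hoxb5, Hoxb6, Hoxd3 and Hoxd4 were close to 0 and removed by the filter. The most counts among them were 8 at 0 h and 10 at 96 h (Hoxb3), so the list values do not describe these HOX genes. For that list the camera adjusted p was 0.815, the median -0.13 (0.65 without the filter, 0.68 with DESeq2 and -0.38 after removal of a GC and length trend) and the mean 0.09.

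Neuronal cytoskeleton and adhesion genes divided into 11 higher and 10 lower of 23 tested (7 and 12 with library size only, 11 and 6 with upper-quartile factors). Prph, the intermediate filament peripherin, rose 1.84-fold (log2 fold change 0.88 ± 0.05), Kif5a, a kinesin heavy chain, rose 1.85-fold and Gap43, a growth cone protein, rose by a log2 fold change of 0.68 ± 0.06. Ncam1 (-1.16 ± 0.04), Map1b (-0.97 ± 0.04) and Tubb3 (-0.57 ± 0.04) fell. Map2 had a log2 fold change of -0.05 ± 0.07 (0.03 with upper-quartile factors) and did not pass, but with library size only it was lower (-0.30, adjusted p = 0.00521). Nefm had 11 counts at 0 h and 1 at 96 h and was removed by the filter (edgeR adjusted p = 0.193 without it). Of 31 synaptic genes, 13 were higher, with Dlg2 (2.88-fold) and Syt4 (2.40-fold), and 9 lower, with Cplx2 (-1.34 ± 0.06) and Syn2 (-1.09 ± 0.06). With library size only, 7 synaptic genes were higher and 15 lower. Syn1 rose (0.27 ± 0.06, a call lost with library size only, at 0.02 and adjusted p = 0.848) and Snap25 did not pass (0.01 ± 0.09, and -0.25 with library size only). Camera passed neither list (adjusted p = 0.837 and 0.762), and the median and mean of the cytoskeleton list were -0.05 (0.22 without the filter and 0.24 with DESeq2) and 0.11.

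Of 14 dense-core vesicle genes 9 rose, including the secretogranins Scg2 (2.57-fold) and Scg5 (2.25-fold), and 2 fell, Chga (-0.76 ± 0.07) and Pam (-0.48 ± 0.06), against 8 and 4 with library size only. Camera passed this list (adjusted p = 0.0233), though the adjusted p = 0.492 with an estimated correlation. Of 26 voltage-gated channel genes 15 rose (16 adjusted over the list alone) and 3 fell (9 and 5 with library size only). Hcn4, a pacemaker channel gene, rose 11.2-fold and Cacna1b, an N-type calcium channel gene, 1.79-fold, while Scn3b (-0.55 ± 0.08) and Kcnh2 (-0.35 ± 0.06) fell. Camera passed the channel list (adjusted p = 0.0155), though the adjusted p = 0.225 with an estimated correlation. For the other lists, unless a second count is given, counts adjusted over the list alone were equal to those over all genes tested. Gm26917 and structural RNA took larger shares of the 96 h libraries (30.5% and 5.71%) beside each of these groups.

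Genes of transmitter and lineage identity were lower more often than higher in the sympathetic list. Of 15 tested members 9 fell, among them Gata2 (-1.77 ± 0.06) and Tbx2 (-1.31 ± 0.06), and 3 rose, among them Cyb561 (1.35 ± 0.16) and Gch1 (0.50 ± 0.06). Th, the rate-limiting enzyme of catecholamine synthesis, stayed below 1 CPM in the mean of both groups (log2 fold change -0.14 ± 0.57, not past the test, and above 0 without 0 h replicate 2, 0 h replicate 3 or 96 h replicate 1, at 0.11, 0.10 and 0.12). The camera adjusted p was 0.0759, and 0.0484 without 96 h replicate 3. In the cholinergic list Chrna7, a nicotinic receptor subunit, fell (-2.67 ± 0.12), Prima1 (0.99 ± 0.08) and Lhx4 (1.62 ± 0.38) rose and 8 did not pass (adjusted p = 0.211). Chat had 0 counts in all libraries. Of 8 GABA and glutamate genes, 3 rose, including Gabbr1 (0.80 ± 0.06) and Grik5 (0.62 ± 0.06), and 2 fell, with a camera adjusted p of 0.674.

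Neurogenic factors included 3 higher of 12 (4 adjusted over the list alone), with Myt1 (0.77 ± 0.06) and Scrt2 (0.88 ± 0.20), and 6 lower, with St18 (-2.54 ± 0.10) and Myt1l (-1.16 ± 0.07). Neurod1 (4 counts at 0 h and 1 at 96 h) was removed by the filter (edgeR adjusted p = 0.561 without it). In the progenitor and Notch list 12 of 22 fell, with the inhibitors of differentiation Id3 (-2.56 ± 0.15) and Id2 (-1.79 ± 0.10) and the proto-oncogene Mycn (-0.62 ± 0.08), and 6 rose, with Hmga1 (0.43 ± 0.06) and Nes (0.26 ± 0.05), against 3 higher and 13 lower with library size only, which ended the call of Nes (0.01, adjusted p = 0.903). Of 22 splicing regulators 11 fell, with Mbnl1 (-0.89 ± 0.05) and Ptbp1 (-0.88 ± 0.05), a repressor of neuronal exons, and 5 rose, with Celf5 (0.96 ± 0.09) and Nova2 (0.57 ± 0.05). Of 28 guidance and neurotrophic genes 12 rose, with Alk (1.06 ± 0.07) and Slit2 (0.88 ± 0.06), and 9 fell, with Plxna4 (-1.11 ± 0.05) and Ret (-0.98 ± 0.04), a receptor tyrosine kinase (7 higher and 10 lower with library size only). None of these 4 lists passed camera (adjusted p = 0.377, 0.143, 0.377 and 0.674). The splicing list had a median of -0.13 and a mean of 0.04.

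Genes of DNA replication fell nearly throughout. Of 41 tested, 39 fell (41 adjusted over the list alone) and none rose (edgeR, and 0 also at an unadjusted p under 0.05 and with DESeq2 or limma-voom). Pcna, the sliding clamp of DNA polymerase, went from 149 ± 0.81 to 57.8 ± 2.5 CPM (log2 fold change -1.37 ± 0.05), Mcm6 had -0.96 ± 0.05 and Mcm2 -0.87 ± 0.04. Camera passed this list (adjusted p = 1.07e-12), though the adjusted p = 0.225 with an estimated correlation. Of 40 G2/M and mitosis genes 26 fell, with Mki67 (-1.11 ± 0.06) and Kif23 (-1.03 ± 0.06), and 4 rose, with Ccnb2 (0.69 ± 0.11) and Hmmr (0.40 ± 0.06). Ccnb1 did not pass (-0.05 ± 0.06, and 0.03 with upper-quartile factors). With library size only, 1 mitosis gene was higher and 33 were lower, Ccnb1 among the lower (-0.30, adjusted p = 8.00e-04), and Hmmr did not pass (0.15, adjusted p = 0.0747). The mitosis list also passed camera (adjusted p = 7.40e-04), though the adjusted p = 0.263 with an estimated correlation. Among 25 CDK inhibitor, RB family and p53 target genes 8 rose, with Trp53inp1 (10.8-fold), Gadd45a (6.07-fold) and Cdkn1a (1.74-fold), and 10 fell, with Ccng1 (-1.03 ± 0.12) and Rbl1 (-0.80 ± 0.09). Cdkn1b (-0.12 ± 0.08) did not pass, though it did without 0 h replicate 3 (adjusted p = 0.0471) and with library size only (-0.37, adjusted p = 0.00392). With library size only, 6 were higher and 13 lower. The list's camera adjusted p was 0.902, its median -0.07 and its mean 0.20.

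**Figure D3:**
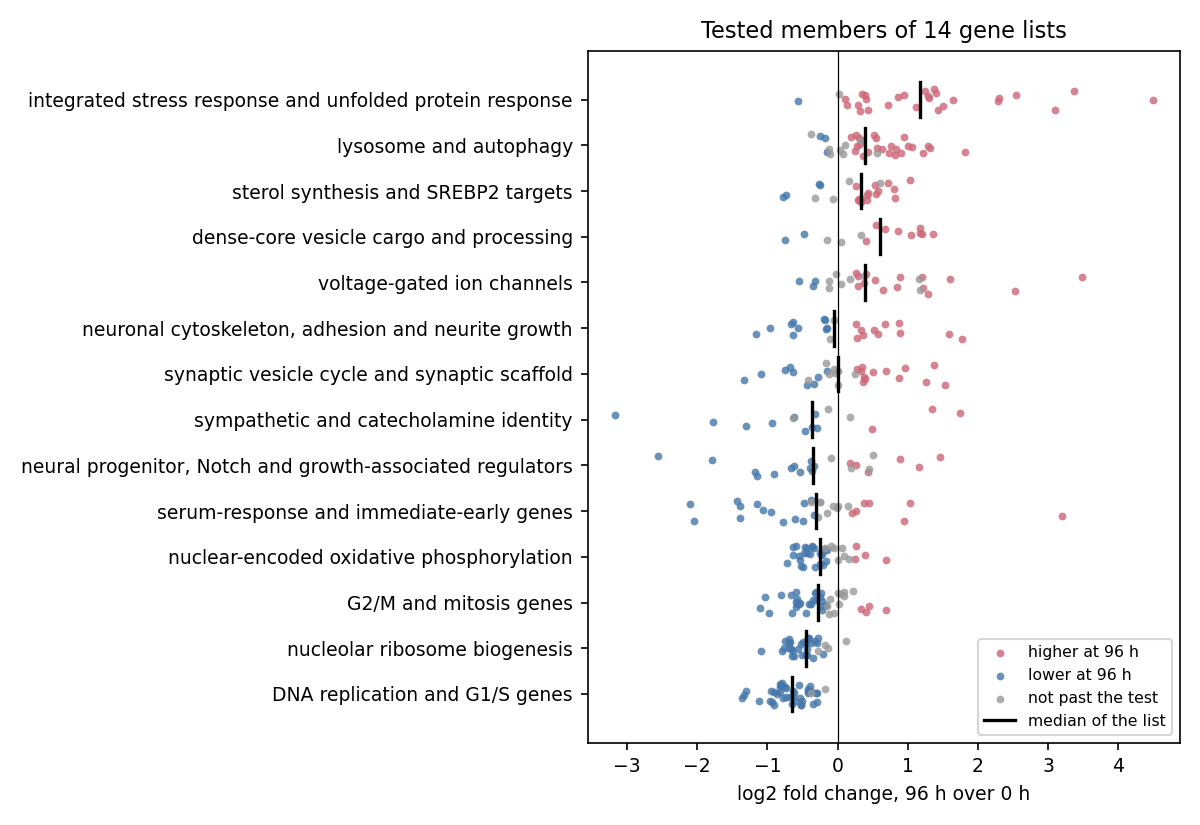
Log2 fold change (96 h over 0 h) of the tested members of 14 gene lists, with a point per gene coloured by its test and a black bar at the list's median. The stress response list has a median of 1.18 and the DNA replication list of -0.64.

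Genes of the integrated stress response and unfolded protein response rose, 26 of 28 tested, with a median fold of 2.26. Slc7a11, the cystine transporter subunit, rose 22.5-fold (from 5.21 ± 1.2 to 119 ± 4.3 CPM), and Ddit3, which encodes the transcription factor CHOP, 8.59-fold (from 11.1 ± 1.1 to 95.5 ± 1.5 CPM). The other higher members included Atf4, Trib3, Chac1, Asns, Psph and Sars1. Creld2 fell (-0.56 ± 0.10), and 1 gene did not pass. The list passed camera (adjusted p = 6.18e-10), though the adjusted p = 0.106 with an estimated correlation. Gm26917 took 30.5% of counts at 96 h against 20.2% at 0 h beside this rise.

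Nucleolar ribosome biogenesis genes moved the other way, with 29 of 33 lower (30 adjusted over the list alone, with 1 higher) and none higher (edgeR, 1 at an unadjusted p under 0.05, and 0 with DESeq2 or limma-voom). Nop58, a core protein of snoRNA particles, fell (-1.10 ± 0.06), as did Wdr43 (-0.75 ± 0.05). Ribosome biogenesis passed camera (adjusted p = 2.52e-08), though the adjusted p = 0.225 with an estimated correlation. Nuclear-encoded oxidative phosphorylation genes fell in 25 of 36 (26 adjusted over the list alone), with Uqcrfs1 (-0.72 ± 0.06) and Atp5f1a (-0.64 ± 0.04), and rose in 4, with Ndufa1 (0.69 ± 0.11) and Cox6a1 (0.40 ± 0.06), against 29 lower and 1 higher with library size only, where Cox6a1 did not pass (0.14, adjusted p = 0.125). Oxidative phosphorylation passed camera (adjusted p = 7.40e-04), though the adjusted p = 0.451 with an estimated correlation. Glycolysis and hypoxia genes divided into 10 higher, with Vegfa (1.51 ± 0.06) and Eno2 (1.32 ± 0.08), and 9 lower, with Ldha (-0.78 ± 0.04) and Pgam1 (-0.73 ± 0.05), of 25 (7 and 15 with library size only, camera adjusted p = 0.865, median -0.01, mean 0.05).

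Lysosome and autophagy genes rose in 25 of 36 (26 adjusted over the list alone) and fell in 3 (17 and 7 with library size only). Gabarapl1, an autophagosome protein, rose 3.51-fold and Sqstm1, an autophagy receptor, 1.92-fold. Wipi1 (-0.26 ± 0.09) and Atp6v0d1 (-0.18 ± 0.06) fell by small amounts, and their calls were lost when 0 h replicate 2 or 0 h replicate 3 was left out, and also without 96 h replicate 2 for Wipi1 and without 96 h replicate 3 for Atp6v0d1. Upper-quartile factors ended both calls (adjusted p = 0.113 and 0.210), and a fit on coding genes alone, chosen after seeing the data, that of Atp6v0d1 (0.0541). Lysosome genes passed camera (adjusted p = 1.96e-04), though the adjusted p = 0.230 with an estimated correlation. Of 24 sterol synthesis genes 16 rose (17 adjusted over the list alone), with Msmo1 (1.04 ± 0.08) and Fdps (0.82 ± 0.06), and 4 fell, with Ebp (-0.78 ± 0.16) and Idi1 (-0.74 ± 0.08), against 7 and 5 with library size only. The camera adjusted p was 0.0370, the adjusted p = 0.230 with an estimated correlation, and the call was lost without 0 h replicate 1, 2 or 3 (adjusted p = 0.0524, 0.0744 and 0.0642). Of 17 fatty acid genes 9 rose, with Scd2 (1.38 ± 0.04) and Lpin1 (1.86 ± 0.08), and 5 fell, with Fasn (-0.69 ± 0.05) and Acly (-0.41 ± 0.04), against 8 and 7 with library size only, and camera did not pass (adjusted p = 0.166).

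Serum-response and immediate-early genes fell in 14 and rose in 7 of 30 (19 and 4 with library size only). Nr4a3 (-2.05 ± 0.10) and Srf (-1.15 ± 0.07), the serum response factor, fell, and Atf3 (3.19 ± 0.19) and Dusp4 (0.38 ± 0.04) rose, the last not past the test with library size only (0.13, adjusted p = 0.0639). The camera adjusted p was 0.0599, and it passed without 0 h replicate 2, 0 h replicate 3, 96 h replicate 2 or 96 h replicate 3 (adjusted p = 0.0343, 0.0487, 0.0465 and 0.0484). Extracellular matrix genes fell in 11 of 18, with Fn1 (fibronectin, -1.48 ± 0.05) and Loxl2 (-1.24 ± 0.05), and rose in 5, with Mmp9 (3.25 ± 0.42) and Itga5 (1.21 ± 0.17), at a camera adjusted p of 0.125. Of 17 interferon and MHC class I genes 6 rose, with H2-K1 (0.73 ± 0.07) and Stat2 (1.06 ± 0.14), and 1 fell, at a camera adjusted p of 0.143.

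Genes grouped by RNA class from the GRCm38.p6 RefSeq biotypes, classes chosen after the data were seen, moved upward where the RNA is structural. Of 124 snoRNA genes, which guide RNA modification, 116 rose (median log2 fold change 2.32), as did 60 of 67 snRNA genes (2.03), 10 of 10 small Cajal body RNA genes (2.36), 17 of 21 nuclear tRNA genes (2.16), 15 of 17 mitochondrial tRNA genes (2.44) and 14 of 15 5S rRNA genes (2.29), with 0 lower in each (edgeR). All 13 mitochondrial mRNAs rose (median 0.81). Of 862 lncRNA genes 237 rose and 58 fell (median 0.48), against 160 and 92 (0.22) with library size only and 263 and 44 (0.56) with upper-quartile factors. These medians kept their sign under each scaling, and with library size only 57 snRNA genes were higher and 1 lower. Reads of snRNA, tRNA and 5S genes can be split among near-identical copies, so single members are uncertain.

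**Figure D4:**
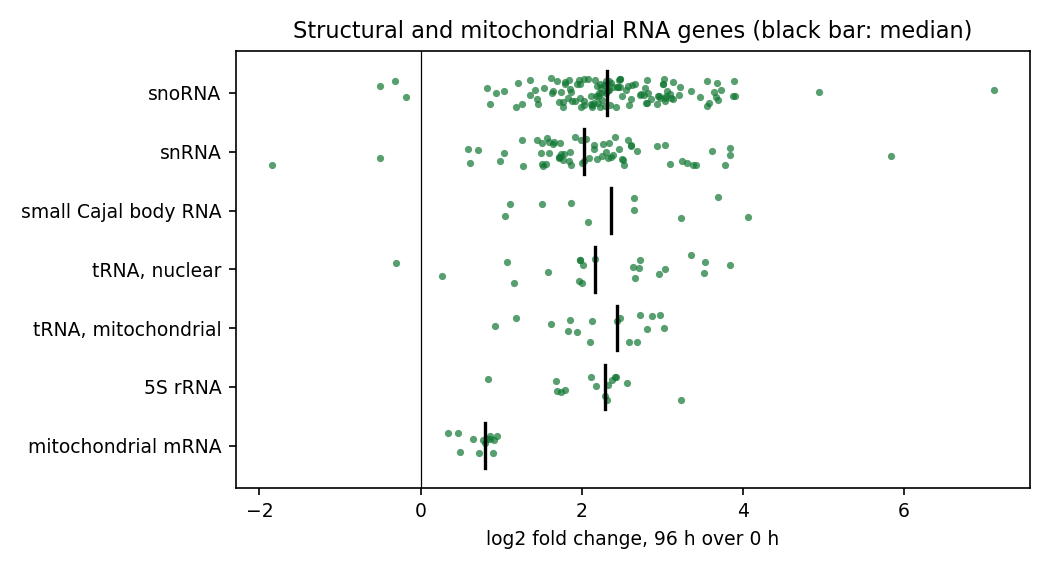
Log2 fold change (96 h over 0 h) of tested genes in 7 classes of structural and mitochondrial RNA, with a point per gene and a black bar at the class median. The median was 2.32 for snoRNA and 0.81 for mitochondrial mRNA, and both stayed above 0 under each scaling.

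Markers of other cell types were few, and their lists did not share a direction. Of the astrocyte markers 3 were tested and all 3 fell, with Sox9 (-0.91 ± 0.07) and Fgfr3 (-0.66 ± 0.17). Of 7 oligodendrocyte and Schwann markers Pdgfra (1.62 ± 0.21) and Erbb3 (1.35 ± 0.26) rose and Pmp22 (-1.07 ± 0.06) fell (2 and 2 with library size only, camera adjusted p = 0.865). Of 6 fibroblast, muscle and endothelial markers 3 rose, with Pdgfrb (2.11 ± 0.21) and Des (1.38 ± 0.40), and Acta2 fell (camera adjusted p = 0.660). The call of Des was lost without 96 h replicate 2 (adjusted p = 0.0642). None of 3 tested immune markers passed (edgeR, and 0 also at an unadjusted p under 0.05 and with DESeq2 or limma-voom). Of 2 tested pluripotency markers Zfp42 rose (0.99 ± 0.35), a call lost without 0 h replicate 1, 96 h replicate 2 or 96 h replicate 3 (adjusted p = 0.0986, 0.0832 and 0.0916) and with library size only, without the filter or with DESeq2 (0.0880, 0.0535 and 0.0719).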

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

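The fit on protein-coding genes alone and the list medians after removal of a GC and length trend were chosen after seeing the data, and all other alternatives were planned. The numbers of genes stayed within 1.5 times of 3927 higher and 3942 lower, and of 1608 and 517 by at least 2-fold, except in 2 settings. Scaling by library size only gave 2409 higher genes and 1021 lower by at least 2-fold, and that scaling moves every gene by about the same shift. The test against a fold of 1.5 gave 1515 higher and 852 lower, by its construction. Leaving out each library in turn gave 3458 to 3796 higher and 3683 to 3807 lower genes. No sign of pairing by replicate number was seen (correlations of deviations from -0.0136 to 0.0144 for equal numbers, and not every library correlated best with its own number). Correlations this small do not exclude pairing. With the replicate number as a block, 3854 genes were higher and 3858 lower, the sterol list had an adjusted p of 0.0522 and the immediate-early list 0.0475.

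An estimated correlation ended each of the 9 camera calls on the lists fixed before the data were examined: dense-core vesicles 0.492, ion channels 0.225, DNA replication 0.225, mitosis 0.263, sterol synthesis 0.230, stress response 0.106, oxidative phosphorylation 0.451, ribosome biogenesis 0.225 and lysosome 0.230 (adjusted p). The sterol list also did not pass with library size only (0.0902) or without the filter (0.0819), nor the dense-core list without the filter (0.0693). The sympathetic and immediate-early lists passed with upper-quartile factors (0.0452 for both) and without the filter (0.0125 and 0.00284). When each library was left out, the adjusted p ran from 0.0289 to 0.0744 for the sterol list, 0.0343 to 0.0576 for the immediate-early list and 0.0484 to 0.0930 for the sympathetic list. The cause of these changes was not tested.

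The test fry asks whether a list's genes move one way, without comparing them with other genes. It passed each list that camera had called, in the same direction (fry adjusted p from 4.47e-06 for stress response to 0.00178 for oxidative phosphorylation). It passed further lists in the direction camera gave: retinoid 6.71e-05, synapse 0.00753, sympathetic 7.09e-05, GABA and glutamate 0.00753, neurogenic factors 0.00139, progenitor and Notch 7.09e-05, splicing 0.00181, fatty acid 7.09e-05, immediate-early 7.72e-05, interferon 0.00387 and extracellular matrix 1.96e-04. It gave the opposite direction for the CDK inhibitor and p53 list (higher, 0.00279) and for the fibroblast, muscle and endothelial markers (lower, 0.0401), neither of which camera had called. With no call on either side, the direction turned with fry for HOX (0.345), guidance (0.335), glycolysis (0.592) and oligodendrocyte genes (0.426), with library size only for CDK inhibitor genes (0.948), without the filter for HOX and cytoskeleton genes (0.995 for both), with the filter of 1 CPM for glycolysis (0.915), and with coding genes alone for CDK inhibitor genes (0.897) and glycolysis (0.831). When each library was left out, the direction of the fibroblast and oligodendrocyte lists turned once each (adjusted p from 0.533 to 0.942 and from 0.708 to 0.920).

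Of 138 tested named genes, 97 kept their direction and side of the threshold in all settings that gave a value. Of 2482 alternative values, 2398 were the same in both respects, 68 no longer passed, 4 newly passed and 12 turned direction, all 12 in genes past the test in neither setting. These were Map2 and Ccnb1 with upper-quartile factors (0.0313 and 0.0302), Snap25 with library size only, without the filter and with DESeq2 (-0.247, -0.0301 and -0.0234), and, over the fits without each library, Map2 (-0.0950 to 0.00336), Snap25 (-0.107 to 0.0551) and Th (-0.655 to 0.117). With library size only, the list medians of GABA and glutamate, fatty acid, guidance, synapse and oligodendrocyte genes fell below 0, and with upper-quartile factors those of cytoskeleton, glycolysis and CDK inhibitor genes rose above 0. Without the filter and with DESeq2, where more low-count members enter, the medians turned positive for HOX (0.65 and 0.68), neurogenic (0.09 and 0.10) and cytoskeleton genes (0.22 and 0.24), and that of extracellular matrix genes moved from -0.56 to -0.02 and -0.01. With upper-quartile factors, 5 retinoid genes were higher and 1 lower, 4 and 1 cholinergic, 4 and 5 neurogenic and 27 and 0 lysosome genes. Further medians within 0.1 of 0 changed sign in single fits for the synapse, glycolysis, cytoskeleton and oligodendrocyte lists. Camera called none of the lists whose median changed sign. Removal of a GC and length trend moved the medians of the 9 tested HOX genes and cofactors from -0.13 to -0.38 and of interferon genes from 0.41 to 0.09, and those of synapse and oligodendrocyte genes fell below 0 (-0.06 and -0.09). The filter removed Rarb, Cyp26a1, Dhrs3, Crabp2, Neurod1 and Nefm, none of which passed without it (adjusted p = 0.193 to 0.792), and Chat had 0 counts.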

Other observations

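The gene families of the next 2 paragraphs, and the tests on ribosomal RNA removal, on coding RNA per structural RNA, on recovery of short RNA and on background reads, the fitted GC and length trend of single genes, the comparison of snoRNA host genes with the snoRNA interval and the counts of large changes under other scalings were chosen after the results were seen. The other tests were written down before the values they measure were seen, although the value of Sars1, one of the synthetase genes, was already known from the stress response list.

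Replication-dependent histone genes fell in 64 of 65 cases, with a median log2 fold change of -1.49. Their reads can be shared among near-identical copies. Genes of the mitochondrial ribosome fell in 45 of 78 cases and rose in 2 (median -0.32), and proteasome subunit genes fell in 24 of 37 and rose in 2 (median -0.30). Cytosolic ribosomal protein genes divided into 27 higher and 21 lower of 79 (median 0.04, and -0.21 with scaling by library size only, which gave 4 higher and 47 lower, while upper-quartile factors gave 37 and 11).

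Among 18 tested genes of the actin cytoskeleton and linked to SRF, 15 fell and 1 rose (mean log2 fold change -1.80), among them Vcl (vinculin, -1.84 ± 0.05) and Actb (-0.79 ± 0.04). All 8 tested feedback and ID genes of BMP and TGF-beta signalling fell (median -2.09), among them Smad6 (-2.75 ± 0.15) and Smad7 (-2.36 ± 0.09). These 4 genes were named after their values were seen, and both sets were partly built from genes already seen among the largest falls, so their counts are no independent evidence of a direction.

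The real grouping gave 7869 genes past the test. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many, the real one, and the highest of the others gave 0 (edgeR). At an unadjusted p under 0.05 the others gave 53 to 110 genes and the real one 8439, and with limma-voom the highest of the others gave 1. With 10 splits the share cannot fall under 0.05. Each of the other splits mixes libraries of both states in each group, so the difference between the states adds to the spread within its groups. Their counts are therefore no baseline for a comparison without a difference.

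Structural RNA genes rose together: 116 of 124 snoRNA genes (median log2 fold change 2.32, 95% bootstrap interval 2.21 to 2.47), 60 of 67 snRNA, 17 of 21 nuclear tRNA and 14 of 15 5S rRNA genes. Poorer removal of ribosomal RNA as the whole cause would leave the snoRNA genes near 0 after scaling. Their median of 2.32 is the pattern itself, known when the bound was written. It shows only that this explanation, as stated, leaves the snoRNA rise unaccounted for, and is no independent test. The excess of the snoRNA median over longer RNAs (7SK, 7SL, RMRP, mt-Rnr1, mt-Rnr2 and Gm26917) was 1.29 (0.942 to 1.84). This excess argues against a loss of coding RNA as the whole cause. Gm26917, whose nature was not tested (0.85), mt-Rnr1 and mt-Rnr2 were the lowest of these longer RNAs and enlarge the excess. 7SK, 7SL and RMRP ran from 1.03 to 1.87, still below the snoRNA interval. Better recovery of shorter RNA predicts a fall of the change with length, which was not seen over 260 structural RNA genes of 53 to 343 nt (Spearman's rho across genes 0.148, permutation p = 0.0181, genes not being independent replicates) nor over the 124 snoRNA genes alone (rho 0.413, permutation p = 1.00e-04), but the same excess of 1.29, for which 7SK, 7SL and RMRP are within that range of lengths, and the medians of 2.44 for mitochondrial tRNA against 0.81 for mitochondrial mRNA and values of 0.53 for mt-Rnr1 and 0.45 for mt-Rnr2, go the way it predicts, so these values point different ways and it cannot be told apart. The snoRNA host genes (Snhg genes and Gas5) had a median of 0.485, under the bound of 0.5 set in advance, with an interval from -0.388 to 1.00 over 15 genes that passes that bound but ends below the 2.21 of the snoRNA genes. The RNA of these 15 hosts thus rose less than the 124 snoRNA genes as a set, which were not matched to the snoRNAs these hosts carry. Counts give the level of host RNA and not its transcription, so higher host transcription cannot be excluded. Other hosts were not taken, and differentiation, the change of medium and a difference in RNA extraction between the groups stay open and untested.

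An ATF4 programme may account for part of the rise of the stress response list (median 1.18). The list also holds genes of the unfolded protein response, such as Hspa5, Xbp1 and Calr. A GC or length trend fitted on all coding genes left a median of 1.08, above the bound of 0.6 set in advance, but with a 95% bootstrap interval (0.317 to 1.33) that reaches below it, so that test alone did not decide. The trend itself reached at most 0.281 in any of 27 members, a value added after the result was seen, and less than the median rise of 1.18, which argues against such a trend as the cause. Cytosolic aminoacyl-tRNA synthetase genes known as ATF4 targets were higher in 11 of 12 cases (median 0.77, Aars1 being the exception at -0.01 ± 0.04), while the other 8 had a median of -0.35 with 6 lower. The difference of medians was 1.11 (exact permutation p = 2.38e-05 for the difference of means across genes, genes not being independent replicates). A difference in this direction is what an ATF4 programme predicts, as a hypothesis. It does not bear on the unfolded protein response members of the list, whose cause was not tested. Retinoic acid cannot be told apart from lower serum, the end of blasticidin or time in culture, since 0 libraries differ in retinoic acid alone.

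Coding genes had more large rises than large falls (1047 against 462 by at least 2-fold) on the TMM scale, and fewer with library size only (713 against 913). Among 7762 nuclear coding genes with a mean of at least 10 CPM the numbers were 299 and 286, a ratio of 1.05 (95% interval 0.886 to 1.23), so on this scale the excess lay in less abundant genes, with 584 against 145 from 1 to 10 CPM and 164 against 31 under 1 CPM. From 10 CPM there were 193 against 628 with library size only and 355 against 237 with upper-quartile factors, so whether more abundant genes share the excess depends on the scaling. Under 10 CPM rises outnumbered falls under each scaling. The numbers were 748 against 176 with TMM, 739 against 176 with DESeq2 size factors, 846 against 155 with upper-quartile factors and 520 against 285 with library size only. Background reads over silent genes could raise such genes at 96 h, and olfactory and vomeronasal receptor genes, taken as silent, were 1.63 times higher in CPM at 96 h, with a counting interval of 1.49 to 1.77 below the 2-fold that the explanation needs, but an interval over libraries of 1.19 to 2.24 that reaches it. The 1487 receptor genes together held 13.4 to 17.6 CPM in the libraries at 0 h and 21.7 to 28.7 CPM at 96 h, far below 1 CPM per gene. Background of that size per gene would fall short of the excess from 1 to 10 CPM. Whether other silent genes carry background at the level of the receptor genes was not tested, so this does not decide. Under 1 CPM, background cannot be told apart from expression of low-abundance genes, because 3 libraries per group leave that ratio too uncertain.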
